A study of Mus musculus with 12 samples.

How the data were processed

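RNA was sequenced from the brains of aged male APPswe mice in 12 libraries, each from 1 mouse per the series description, in 4 groups of 3. Tests treat the libraries as separate mice, and their p would be too small if libraries shared material. Per the labels, total RNA was extracted with the Arcturus PicoPure kit, and linear amplification of the RNA, library preparation and sequencing were done by a service laboratory. The series description gives the tissue as the whole hippocampus of the right hemisphere, whereas the sample source label names the brain meninges. Because these descriptions differ, marker genes of hippocampus and of meninges were measured in each library.

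The deposited table holds raw read counts per gene for each of the 12 libraries, with no normalization by the authors. FastQC, Trim Galore, STAR, Subread, featureCounts and edgeR are named in the submitters' processing notes together with the mouse genome build mm10. Their versions, the gene annotation, the treatment of reads that map to several places and whether counting used the strand are not given in the sources used here. Counts of paralogs and pseudogenes (H2-K1 and H2-D1, C4b, Ifit1 and Ifit3, Mt1 and Mt2, Lyz2, Lamr1-ps1) and of genes that overlap another gene are therefore uncertain. The table holds 14881 Ensembl gene identifiers, and the lowest total of a gene over the 12 libraries was 147 reads. The deposited table thus held no gene with only a few reads, and the filterByExpr function of edgeR removed no gene from it. Gene symbols, coordinates, GC content and transcript lengths came from GENCODE M21 on GRCm38 (mm10), which named 14791 identifiers and left 90 without a symbol.

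Library totals ran from 23213612 to 29295266 reads. The common biological coefficient of variation was 5.16%. Molecular identifiers are not given in the sources used here, so counting precision at this depth describes reads, not molecules.

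The counts were fitted with edgeR 4.0.16 in R 4.3.3 with TMM scaling, 1 mean per group and all 12 libraries in 1 model. Contrasts were tested two-sided with edgeR's quasi-likelihood test, with Benjamini-Hochberg adjustment over all genes of a contrast and a threshold of 0.05. There were 8 contrasts: the antibody within each vector, the vector within each antibody, the combined treatment against the double control, the interaction, and each treatment averaged over the other. Expression is given as CPM, counts relative to the TMM-scaled library total, as mean ± SD with n = 3 mice per group, and changes are log2 fold changes with their standard error (SE). Levels of a list in a library are means over members of log2 CPM (prior count 2), with each gene centred on its mean over the libraries.

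Before the data were examined, 41 gene lists for cell types, brain regions and pathways were fixed, of which 39 had at least 3 measured members. They were tested with camera (limma 3.58.1, statmod 1.5.0) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. Each was run again with an estimated correlation and with the fry rotation test. For list members, genes that passed after adjustment over the list alone were counted beside those that passed over all genes.

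The rule for named genes was fixed at the same time. For each contrast it took the 10 higher and the 10 lower genes with the smallest p among those that passed. Where fewer than 5 passed in a direction, those that passed were named, followed up to 3 by the next smallest p as not passing. Members of fixed lists that passed were named up to 4 per list. A further 24 genes were followed in every contrast, in full where they passed and as ranges elsewhere: Vegfc, Flt4, App, Apoe, Trem2, Cst7, Clec7a, Itgax, Cd68, Tmem119, P2ry12, Fcgr3, C1qa, C3, C4b, H2-K1, Cd74, Gfap, Aqp4, Cldn5, Ttr, Slc17a7, Gad1 and Mbp. Predicted genes were counted but named only as members of a list. The values of 1 gene that the rule named are not reported here. ENSMUSG00000045999, Prnp, Lamr1-ps1, Fgfbp3, Cpeb3, March5, Gm42418 and Lars2 lie outside the rule and were chosen after their values were seen.

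Alternatives fixed in advance were DESeq2 size factors in place of TMM, no filter on low counts, the DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, fits of only the groups compared, the mean level of choroid plexus markers as a covariate, and each library left out in turn. Alternatives added after seeing the data left out sets of libraries or corrected each library for trends with GC content and transcript length. The tests were tried on simulated counts for the combined treatment against the double control, with 200 of 14881 genes changed. For changes of 1.25, 1.5 and 2 times, 41%, 83% and 92% of them were recovered with 12 libraries, beside 4, 13 and 7 false calls. With 8 libraries, 26%, 73% and 87% were recovered, beside 12, 15 and 11 false calls. The simulated libraries were independent and drawn with the dispersions of all 12 real libraries. The common biological coefficient of variation was 5.16% in these 12 and 7.21% in the 8 left without libraries 3, 6, 9 and 12. Recovery with 8 libraries may thus be overstated, and false calls from libraries that share material were not simulated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.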

Results

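RNA of the hippocampus, per the series description, was sequenced from 12 male APPswe mice aged 22 to 26 months, a strain with an amyloid precursor protein transgene. Each mouse received 5 µL of an adeno-associated virus (AAV1) into the cisterna magna, a space filled with cerebrospinal fluid. The vector encoded enhanced green fluorescent protein (eGFP) as control or mouse vascular endothelial growth factor C (mVEGF-C), a growth factor for lymphatic vessels. Weekly intraperitoneal injections of 40 mg/kg followed, of either control immunoglobulin (mIgG) or mAducanumab (mAdu), an antibody against aggregated amyloid beta. The title of the series frames the question as whether lymphatic vessels of the meninges modify such immunotherapy. The 4 groups of 3 mice were eGFP+mIgG (mice 1 to 3), eGFP+mAdu (mice 4 to 6), mVEGF-C+mIgG (mice 7 to 9) and mVEGF-C+mAdu (mice 10 to 12), with 1 library per mouse and 23213612 to 29295266 counted reads per library.

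Markers of hippocampal regions were abundant in the 12 libraries. The median level ran from 97.6 to 111 CPM over 8 CA1 pyramidal markers, from 41 to 53.9 CPM over 11 CA3 markers and from 48.5 to 60.8 CPM over 13 dentate granule cell markers. Over 18 markers of meningeal and perivascular fibroblasts it ran from 4.05 to 9.27 CPM, over 6 lymphatic endothelial markers from 8.49 to 10.7 CPM and over 12 choroid plexus markers from 1.17 to 2.15 CPM. The lymphatic endothelial list shares Prox1 with the dentate granule cell list, so neither its level nor its tests describe lymphatic vessels alone. Medians of markers of neighbouring regions were 25.1 to 42.4 CPM for neocortex, 9.81 to 13.3 CPM for striatum and 5.41 to 6.92 CPM for thalamus. The Y-linked genes Ddx3y (114 to 134 CPM), Eif2s3y (34.3 to 41.6 CPM), Kdm5d (29.9 to 34 CPM) and Uty (35.9 to 47 CPM) were present in each library, which matches the male label.

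Vegfc itself, the gene carried by the treatment vector, was not higher in the hippocampus of mice given it. Its level was 3.41 ± 0.188 CPM in eGFP+mIgG, 3.29 ± 0.188 CPM in eGFP+mAdu, 2.72 ± 0.825 CPM in mVEGF-C+mIgG and 2.98 ± 0.407 CPM in mVEGF-C+mAdu (SD, n = 3). Averaged over antibodies, the mVEGF-C vector changed Vegfc by -0.24 (SE 0.124), with an adjusted p = 0.349 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Flt4, the receptor for VEGF-C, lay at 1.39 ± 0.119, 1.36 ± 0.317, 1.32 ± 0.0986 and 1.27 ± 0.123 CPM in the same groups.

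Within each group, 1 library lay between the other 2 for most genes that varied beyond counting noise. These were libraries 3, 6, 9 and 12, with the middle value in 88.9%, 86.6%, 84.6% and 91.5% of such genes, where an equal share is 33.3%. They are called the intermediate libraries in what follows. For most varying genes, leaving them out moves a group mean little, so a kept direction in that setting is no check of a change. Each SD and p treats the 12 libraries as separate mice, as the series description gives them, and would be too small if libraries shared material. The other 8 libraries held the middle value in at most 8.9%. App was at 1342 CPM in mouse 5 and 3716 CPM in mouse 6, against 4721 to 5507 CPM in the other 10 mice. An identifier without a symbol, ENSMUSG00000045999, took 8.59%, 8.51% and 2.44% of the reads of mice 1 to 3 (91440, 91830 and 24410 CPM), against 108.4 to 1037 CPM in the other 9 mice.

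**Figure D1:**
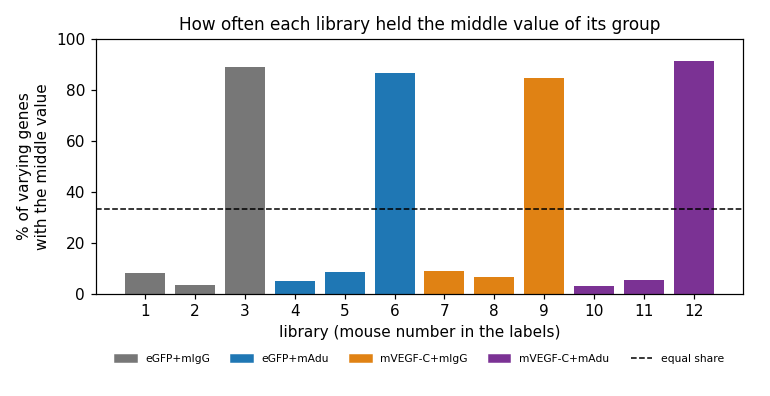
Bars give, for each of the 12 libraries, the percentage of varying genes for which that library held the middle value of its group of 3, and the dashed line gives an equal share of 33.3%. Libraries 3, 6, 9 and 12 stood at 84.6% or above and the other 8 at 8.9% or below.

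What the antibody did with the control vector was asked by comparing eGFP+mAdu with eGFP+mIgG. Ide, which encodes insulin-degrading enzyme, a protease that cleaves insulin and amyloid beta, rose from 71.1 ± 1.34 to 99.5 ± 0.862 CPM (SD, n = 3), a log2 change of 0.48 (SE 0.038). Btaf1, a regulator of the TATA-binding protein, rose from 82.3 ± 2.35 to 112 ± 2.86 CPM (log2 0.45, SE 0.037). Both genes lie on chromosome 19 of mm10, Btaf1 (ENSMUSG00000040565) from 36926079 to 37012752 and Ide (ENSMUSG00000056999) from 37268743 to 37337852. Cdkl4, a cyclin-dependent kinase-like gene, rose from 29.7 ± 1.30 to 37.1 ± 2.00 CPM (log2 0.32, SE 0.052). Vwf, the von Willebrand factor of endothelial cells, fell from 16.1 ± 0.503 to 9.52 ± 1.13 CPM (log2 -0.75, SE 0.094). The 5th gene that passed was ENSMUSG00000045999, high in the mIgG mice as given above (log2 -8.58, SE 0.809). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 1.67e-05 for Ide and for Btaf1, 0.0404 for Cdkl4, 0.00257 for Vwf and 7.84e-05 for ENSMUSG00000045999. Dsp (log2 -0.64, SE 0.114) and Iqgap2 (log2 -0.28, SE 0.050) did not pass, with adjusted p of 0.0838 and 0.0871 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the 24 genes followed throughout, none passed by that test, with changes from -0.57 for App to 0.24 for Cd74. App in mouse 5 of eGFP+mAdu was at 25.6% of the median of the 10 mice other than 5 and 6. Without these 2 mice the group is mouse 4 alone, which is too few for a check of its differences.

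With the control vector, 5 fixed lists were higher and 6 lower with mAdu by camera at its preset correlation. Markers of excitatory neurons (16 measured, median log2 -0.10, camera adjusted p = 7.86e-05) and of dentate granule cells (13, median -0.12, camera adjusted p = 0.000112) were lower as sets, and both calls were lost with an estimated correlation (adjusted p = 0.162 with an estimated correlation for each). Over all genes no member of either passed; adjusted over the list alone, 5 of the former fell, and 6 of the latter fell and 1 rose. Striatal markers were higher as a set (10 measured, median 0.35, camera adjusted p = 0.000149), with 4 that rose adjusted over the list alone and 0 over all genes, and this call was lost too (adjusted p = 0.162 with an estimated correlation). The other 8 calls were lost as well, with adjusted p = 0.162 to 0.71 with an estimated correlation. Those for inhibitory neurons, nuclear-encoded respiratory chain, ribosomal proteins and heat shock were also higher, with medians of 0.10, 0.04, 0.04 and 0.04. Those for complement, oligodendrocytes and myelin, border-associated macrophages and the glucocorticoid response were lower, with medians of -0.09, -0.09, -0.39 and -0.12. With the intermediate libraries left out, 2 genes passed, of which 1 was among the 5, and the count of lists was 11. Ide, Btaf1, Vwf and Cdkl4 did not pass there. Adjusted p was 0.0576 for Ide and 0.076 for Btaf1 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The 5 genes kept their direction, with a median absolute log2 change of 0.485 at first and 0.474 in that setting, and a median SE of 0.052 and 0.082. When 1 library was left out at a time, the count of genes ran from 4 without mouse 1 to 35 without mouse 2.

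**Figure D2:**
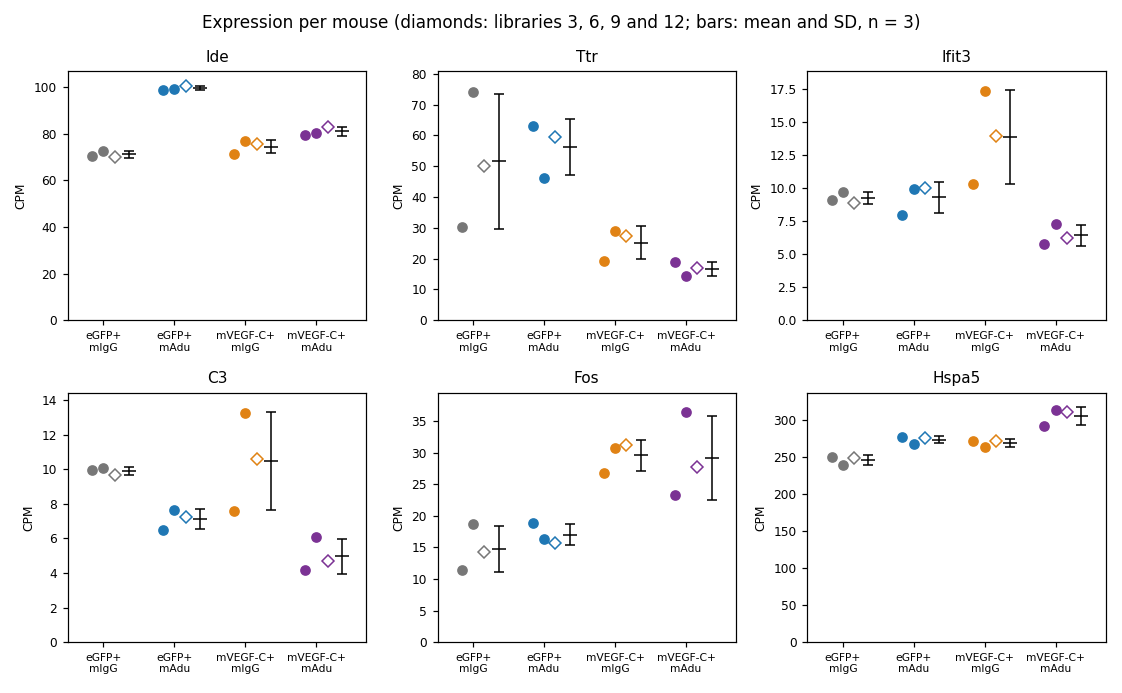
Points give CPM per mouse for 6 named genes in the 4 groups (open diamonds for libraries 3, 6, 9 and 12), and bars the mean and SD of 3 mice. Ide stood at 98.8 to 100.4 CPM in eGFP+mAdu and at 70.2 to 83.1 CPM in the other groups, while Fos was higher and Ttr lower with mVEGF-C than with eGFP on average.

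With the mVEGF-C vector, the antibody comparison (mVEGF-C+mAdu against mVEGF-C+mIgG) gave 31 genes, 10 higher and 21 lower, with immune genes among those that fell. Ifit3, an antiviral gene induced by interferon, fell from 13.9 ± 3.53 to 6.41 ± 0.78 CPM (log2 -1.11, SE 0.157). Usp18 (log2 -2.00, SE 0.311), Irf7 (-1.32, SE 0.239), Ifit1 (-1.30, SE 0.25) and Iigp1 (-1.33, SE 0.199), also induced by interferon, fell too. C3, the central complement component, fell from 10.5 ± 2.81 to 4.96 ± 0.99 CPM (-1.08, SE 0.170), C1qa from 71.8 ± 10.4 to 49.1 ± 2.75 CPM and C1qc from 48.4 ± 4.84 to 33.6 ± 2.59 CPM. The class I genes H2-K1 (-0.70, SE 0.116) and H2-D1 (-0.75, SE 0.141) fell as well. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p of these 10 genes ran from 0.0145 for Ifit3 to 0.0482 for Ifit1.

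Other genes that fell with mAdu under mVEGF-C were Npas4, a transcription factor induced by neuronal activity (13.2 ± 1.30 to 6.21 ± 0.553 CPM, log2 -1.08, SE 0.129), Lcn2 of reactive astrocytes (1.04 ± 0.135 to 0.171 ± 0.0554 CPM, -2.56, SE 0.479) and Mobp of myelin (640 ± 25.3 to 505 ± 6.46 CPM, -0.34, SE 0.061). Rnase4 (-0.44), Lgals3bp (-0.87), Shisa7 (-0.35) and Olfml3 (-0.37) fell as well. Among the 10 that rose, Tacr3, the neurokinin B receptor, went from 2.14 ± 0.329 to 4.86 ± 0.197 CPM (1.18, SE 0.141) and Dsc3, a desmosomal cadherin, from 5.61 ± 0.81 to 10.7 ± 2.46 CPM (0.93, SE 0.161). Agt, the angiotensinogen gene of astrocytes, rose by 0.43, Rspo2 by 0.35, Cbln2 by 0.34, Uba6 by 0.30, Ppp1r3c by 0.29, Ak4 by 0.28, Htr1a by 0.26 and Bmt2 by 0.22. Adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ran from 0.00269 for Tacr3 and Npas4 to 0.0482. Of the 24 genes followed throughout, C1qa, C3 and H2-K1 passed and 21 did not, with changes from -2.52 for Cst7 to 0.15 for App.

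Under mVEGF-C, 11 lists were lower with mAdu and 1 was higher. Other splits of these mice gave a median of 9 list calls and up to 17, so this count does not exclude chance. All 19 measured interferon response genes had a negative change (median log2 -0.72, camera adjusted p = 2.6e-22): 4 fell over all genes and 12 adjusted over the list alone. For antigen presentation (16 measured, 16 negative, median -0.59) these counts were 2 and 10, for complement (13, median -0.44) 3 and 9, and for reactive astrocytes (17, 17 negative, median -0.35) 1 and 10. The 12 choroid plexus markers were also all negative (median -0.44), and 0 passed over either set. These 5 calls held with an estimated correlation, with adjusted p = 0.0498, 0.0447, 0.0213, 0.0447 and 0.0498 with an estimated correlation. Another 7 calls were lost, with adjusted p = 0.163, 0.0649, 0.0723, 0.251, 0.227, 0.767 and 0.0649 with an estimated correlation in the order given next. Lists for disease-associated microglia (27 measured, median -0.27, of which 1 fell over all genes, and 15 fell and 1 rose adjusted over the list alone), homeostatic microglia (15, -0.17), Fc receptors and phagocytosis (18, -0.25), oligodendrocytes and myelin (17, -0.16), ependymal cells (11, -0.41) and ribosomal proteins (28, -0.03) were lower. That for heat shock and the unfolded protein response (14, 0.09) was higher. By fry with Benjamini-Hochberg adjustment, homeostatic microglia (adjusted p = 0.0184), Fc receptors (0.0217) and heat shock (0.0184) of these 7 passed.

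The interferon level was uneven in the mIgG group, at 0.003, 0.594 and 0.365 in mice 7, 8 and 9, whereas mice 10, 11 and 12 with mAdu were at -0.46, -0.333 and -0.416. Choroid plexus markers differed in the same comparison, down to -0.731 in mouse 10. Without the intermediate libraries, 0 genes passed by edgeR's quasi-likelihood test, with 683 at an unadjusted p under 0.05, and 13 lists passed. With the choroid plexus level as a covariate the count was 0, with 952 at an unadjusted p under 0.05. That level was lower in each mAdu mouse (-0.731 to -0.22) than in each mIgG mouse (-0.079 to 0.106), so covariate and group are confounded. The 31 genes kept their direction in both settings, with a median absolute log2 change of 0.703 at first, 0.718 without the intermediate libraries and 0.533 with the covariate, and a median SE of 0.124, 0.179 and 0.208. Leaving out 1 library at a time gave 2 genes without mouse 9 and 138 without mouse 7.

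**Figure D3:**
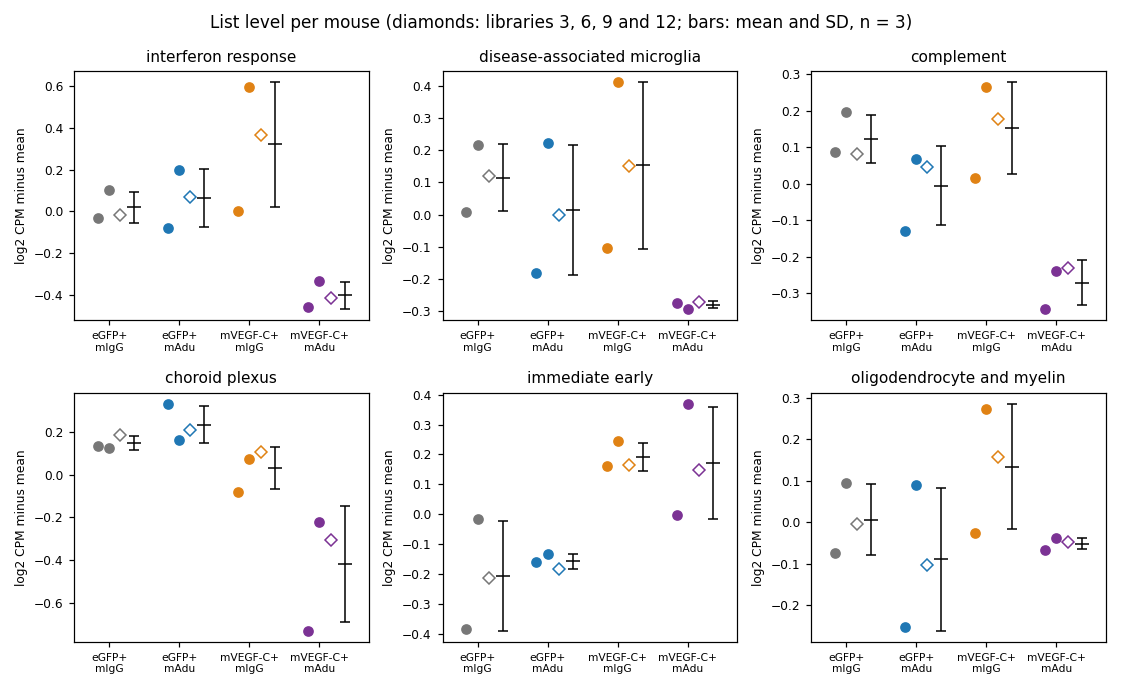
Points give the mean log2 CPM of a list's members, each centred on its mean over the 12 libraries, for 6 fixed lists in each mouse (open diamonds for libraries 3, 6, 9 and 12), with bars for the mean and SD of 3 mice. The interferon level ran from -0.46 to -0.333 in mVEGF-C+mAdu and from 0.003 to 0.594 in mVEGF-C+mIgG.

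The effect of the vector without the antibody was asked by comparing mVEGF-C+mIgG with eGFP+mIgG. Fos, an early transcription factor of active neurons, rose from 14.8 ± 3.68 to 29.6 ± 2.45 CPM (log2 1.02, SE 0.159), and Npas4 rose from 7.08 ± 1.35 to 13.2 ± 1.30 CPM (0.88, SE 0.126). Mobp, of compact myelin, rose from 470 ± 12.8 to 640 ± 25.3 CPM (0.44, SE 0.061), and Bcas1, of newly formed myelinating oligodendrocytes, from 65.4 ± 4.81 to 87.8 ± 5.77 CPM (0.43, SE 0.062). Tacr3 fell from 4.57 ± 0.515 to 2.14 ± 0.329 CPM (-1.09, SE 0.142). With ENSMUSG00000045999 (-7.28, SE 0.764), 6 genes passed, and adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ran from 0.00102 for that identifier to 0.0260 for Fos. Vwf (-0.54, SE 0.093) and Foxo1 (-0.43, SE 0.076) did not pass (adjusted p = 0.0731 and 0.0802 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). None of the 24 genes followed throughout passed, with changes from -1.02 for Ttr to 0.39 for Clec7a.

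Of 24 immediate early genes measured, 20 had a positive change under mVEGF-C with mIgG (median log2 0.42, camera adjusted p = 2.22e-21). Of these 2 rose over all genes and 13 adjusted over the list alone; the call was lost with an estimated correlation (adjusted p = 0.138 with an estimated correlation). Another 9 calls were lost, with adjusted p = 0.138 to 0.729 with an estimated correlation. All 17 oligodendrocyte and myelin genes had positive changes (median 0.11), of which 1 rose over all genes and 1 adjusted over the list alone. Interferon response (19 measured, median 0.19), homeostatic microglia (15, 0.10), mitochondrially encoded (8, 0.09), nuclear-encoded respiratory chain (27, 0.03) and ribosomal protein genes (28, 0.03) were also higher as sets. Meningeal and perivascular fibroblast markers (18 measured, 17 negative, median -0.36), border-associated macrophage markers (4, median -0.66, of which 3 fell adjusted over the list alone) and VEGF ligands and receptors (12, 11 negative, median -0.10) were lower. With libraries 3, 6, 9 and 12 left out, 2 genes and 6 lists passed, and Fos, Npas4, Mobp, Bcas1 and Tacr3 were not among these genes. The 6 genes called at first kept their direction, with a median absolute log2 change of 0.948 at first and 0.925 in that setting. Their median SE was 0.134 and 0.19. When 1 library was left out at a time, 1 gene passed without mouse 9 and 52 without mouse 7, and 6 lists passed without mouse 3. A split of the same mice that set mice 1, 3 and 7 against the rest gave 363 genes.

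The effect of the vector in antibody-treated mice was asked by comparing mVEGF-C+mAdu with eGFP+mAdu. Ttr, which encodes the thyroid hormone carrier transthyretin and is abundant in choroid plexus, fell from 56.2 ± 8.99 to 16.6 ± 2.24 CPM (log2 -1.75, SE 0.244); it lies on chromosome 18 from 20665280 to 20674321 (mm10, ENSMUSG00000061808). Ide fell from 99.5 ± 0.862 to 81.1 ± 1.81 CPM (-0.30, SE 0.038) and Btaf1 from 112 ± 2.86 to 96.1 ± 1.49 CPM (-0.22, SE 0.036). Arl5b, a small GTPase, rose from 39.0 ± 2.85 to 51.2 ± 2.54 CPM (0.39, SE 0.056). The splicing regulator Srsf10 (0.32, SE 0.048), Arrdc3 (0.29, SE 0.044) and Utp14b (0.44, SE 0.071) rose as well. These 7 genes were the calls, with adjusted p from 0.0130 for Ide to 0.0325 for Btaf1 and Utp14b by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the 24 genes followed throughout, Ttr passed and 23 did not, with changes from -2.09 for Cst7 to 0.61 for App. The App value rests on low App in mouse 5 of eGFP+mAdu, at 25.6% of the median of the 10 mice other than 5 and 6. This mouse is part of every comparison that uses eGFP+mAdu.

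Choroid plexus markers were lower as a set in mVEGF-C+mAdu than in eGFP+mAdu (12 measured, 10 negative, median log2 -0.65, camera adjusted p = 2.72e-08). Of these 1 fell over all genes and 5 adjusted over the list alone, and the call held with an estimated correlation (adjusted p = 0.0268 with an estimated correlation). Immediate early genes were higher (24 measured, 22 positive, median 0.23), with 9 that rose adjusted over the list alone and 0 over all genes (adjusted p = 0.149 with an estimated correlation). Antigen presentation (16, all negative, median -0.40) and ependymal markers (11, all negative, median -0.46) were lower, with 10 and 6 that fell adjusted over the list alone (adjusted p = 0.137 and 0.194 with an estimated correlation). Another 12 calls were lost, with adjusted p = 0.104 to 0.53 with an estimated correlation, of which striatum (adjusted p = 0.027) and heat shock (0.0352) passed by fry with Benjamini-Hochberg adjustment. Lists for interferon response (median -0.53), meningeal and perivascular fibroblasts (-0.45), striatum (-0.47), complement (-0.31), reactive astrocytes (-0.24), disease-associated microglia (-0.16), homeostatic microglia (-0.14), Fc receptors and phagocytosis (-0.13) and ribosomal proteins (-0.04) were lower too. Those for heat shock (0.10), excitatory neurons (0.07) and cholesterol synthesis (0.06) were higher. Without the intermediate libraries 0 genes passed by edgeR's quasi-likelihood test, with 758 at an unadjusted p under 0.05, and 15 lists passed. With a correction for GC content and length 4 genes passed, and with the choroid plexus level as a covariate 0 passed, with 756 at an unadjusted p under 0.05. That level was -0.731 to -0.22 in the mVEGF-C+mAdu mice and 0.163 to 0.333 in the eGFP+mAdu mice, so covariate and group are confounded. The 7 genes kept their direction, with a median absolute log2 change of 0.319 at first, 0.31 without the intermediate libraries and 0.459 with the covariate, and a median SE of 0.048, 0.074 and 0.091. Left out singly, libraries gave from 0 genes, a count first reached without mouse 4, to 110 without mouse 5.

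The combined treatment (mVEGF-C+mAdu) differed from the double control (eGFP+mIgG) in 324 genes, 177 higher and 147 lower. The libraries of the double control were also those with ENSMUSG00000045999 at 8.59%, 8.51% and 2.44% of reads and TMM factors of 0.94, 0.927 and 0.998, so this difference between libraries follows the comparison. Lcn2 fell from 1.52 ± 0.0659 to 0.171 ± 0.0554 CPM (log2 -3.11, SE 0.444), Ttr from 51.6 ± 21.9 to 16.6 ± 2.24 CPM (-1.62, SE 0.246) and Vwf from 16.1 ± 0.503 to 9.86 ± 0.825 CPM (-0.71, SE 0.095). Hspa5, the chaperone BiP of the endoplasmic reticulum, rose from 246 ± 6.36 to 305 ± 11.9 CPM (0.31, SE 0.038), and Ppp1r3c, which directs glycogen synthesis, from 66.5 ± 5.49 to 93.4 ± 1.78 CPM (0.49, SE 0.053). Dio2, the deiodinase that activates thyroid hormone, rose from 49.6 ± 5.47 to 68.4 ± 1.03 CPM (0.47, SE 0.064). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 0.000690 for Ppp1r3c, 0.00199 for Hspa5, 0.00343 for Vwf, 0.00420 for Dio2, 0.00570 for Lcn2 and 0.00895 for Ttr. The other 7 leading genes that rose were Rbm12b2 (0.54), Arl5b (0.38), Rngtt (0.34), Washc4 (0.30), Sacm1l (0.25), Rab8b (0.24) and Ppp4r2 (0.23). Among the lower ones were Wnt9a (-0.77), Tgm2 (-0.51), Shisa7 (-0.44), Rnase4 (-0.43), Tab1 (-0.39), Lmtk3 (-0.30) and Pitpnm2 (-0.26).

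Complement genes fell as a group in the combined treatment: 7 of 13 measured fell over all genes and 7 adjusted over the list alone (median log2 -0.41, camera adjusted p = 2.86e-08). C3 fell from 9.92 ± 0.218 to 4.96 ± 0.99 CPM, C4b from 264 ± 34 to 132 ± 14.5 CPM, C1qa from 66.3 ± 4.7 to 49.1 ± 2.75 CPM, C1qb from 46.9 ± 3.19 to 34.6 ± 0.839 CPM and C1qc from 44.9 ± 3.03 to 33.6 ± 2.59 CPM. Of 27 disease-associated microglia genes, 2 fell over all genes, Lgals3bp (-0.65, SE 0.143) and Lyz2 (-1.06, SE 0.260), and 13 adjusted over the list alone. Of 16 antigen presentation genes, all negative, H2-K1 (-0.50, SE 0.117) and Psmb9 (-0.84, SE 0.201) fell over all genes and 5 adjusted over the list alone. Of 19 interferon genes, Ifitm3 fell (-0.64, SE 0.152), and 4 fell adjusted over the list alone. Reactive astrocyte genes fell in 4 of 17 over all genes (Lcn2, Vim, Cp and Aspg) and in 8 adjusted over the list alone. Stab1 of border-associated macrophages (-0.39) and Icam1, an adhesion molecule in the cytokine list (-0.78), also fell. Complement held with an estimated correlation (adjusted p = 0.0403 with an estimated correlation). Microglia, antigen presentation, interferon and reactive astrocytes were lost (adjusted p = 0.363, 0.175, 0.4 and 0.0637 with an estimated correlation). By fry with Benjamini-Hochberg adjustment, antigen presentation (adjusted p = 0.0383) and reactive astrocytes (0.0141) passed, while microglia (0.154) and interferon (0.182) did not.

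Immediate early genes rose in 7 of 24 over all genes and in 13 adjusted over the list alone (median log2 0.34, camera adjusted p = 8.81e-11; adjusted p = 0.177 with an estimated correlation). Fos rose from 14.8 ± 3.68 to 29.1 ± 6.7 CPM, Egr2 from 2.33 ± 0.745 to 6.80 ± 3.09 CPM, Fosb by 0.82 (SE 0.175) and Nr4a1 by 0.67 (SE 0.151). Genes of heat shock and the unfolded protein response rose in 3 of 14 over all genes, Hspa5, Xbp1 (0.21, SE 0.046) and Hsp90aa1 (0.19, SE 0.042), and in 6 adjusted over the list alone (adjusted p = 0.0403 with an estimated correlation). Choroid plexus markers Ttr and 1500015O10Rik (-0.93, SE 0.181) fell, 2 of 12 over all genes and 5 adjusted over the list alone (median -0.56, adjusted p = 0.0403 with an estimated correlation). Of 11 ependymal markers Tekt1 (-0.68, SE 0.122) and Foxj1 (-0.55, SE 0.131) fell over all genes and 9 adjusted over the list alone (adjusted p = 0.195 with an estimated correlation). Of 18 meningeal and perivascular fibroblast markers 17 were negative, with 0 that fell over all genes and 11 adjusted over the list alone (adjusted p = 0.343 with an estimated correlation). Border-associated macrophages (median -0.62), Fc receptors (-0.21), homeostatic microglia (-0.11) and dentate granule cells (-0.11) were lower as sets at the preset correlation, with adjusted p = 0.179, 0.195, 0.522 and 0.363 with an estimated correlation. By fry with Benjamini-Hochberg adjustment, immediate early genes, ependymal markers, border-associated macrophages and Fc receptors passed (adjusted p = 0.0383 for each). Fibroblasts (0.154), homeostatic microglia (0.154) and dentate granule cells (0.186) did not pass by fry. Single members of lists that passed were Aldh1l1 (-0.21), Tagln (-1.09), Elavl2 (0.25), Homer1 (0.35), Sox11 (0.33), Ide (0.19), Aph1b (0.22), Cyp51 (0.24), Mt1 (-0.32), Mt2 (-0.57) and Nr1d2 (0.26).

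Of the 24 genes followed throughout, C1qa, C3, C4b, H2-K1 and Ttr passed in the combined treatment. The other 19 had changes from -2.35 for Cst7 to 0.12 for Gad1, and their lowest adjusted p, for Cst7, was 0.0564 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Apoe was at 1445 ± 84.9 and 1294 ± 17.6 CPM, Trem2 at 14.6 ± 1.12 and 11.5 ± 0.769 CPM, Clec7a at 2.50 ± 0.596 and 1.28 ± 0.187 CPM and Gfap at 407 ± 64.6 and 322 ± 6.72 CPM in control and combination. The genes that rose had a median GC content of 42.1% and those that fell of 55.0%, against 49.7% over all genes; with a correction for GC content and length, 98 genes passed, of which 83 were among the 324. In the 8 other libraries 2 genes and 13 lists passed, and with the choroid plexus level as a covariate 2 genes passed. That level was lower in each mouse of the combination (-0.731 to -0.22) than in any other mouse (-0.079 to 0.333). Covariate and group are thus confounded, and the lost calls do not show a choroid plexus cause. The 324 genes kept their direction, with a median absolute log2 change of 0.262 at first and 0.271 and 0.252 in these settings, and a median SE of 0.055, 0.081 and 0.103. Leaving out the intermediate libraries could hardly move a group mean, so the kept direction there is no check. When 1 library was left out at a time, 12 genes passed without mouse 12 and 594 without mouse 7.

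Whether the antibody effect differed between vectors was tested as the interaction, for which 2 genes passed. The mAdu effect on Ide was smaller with mVEGF-C by 0.36 on the log2 scale (interaction -0.36, SE 0.054), with group means of 71.1, 99.5, 74.5 and 81.1 CPM. The adjusted p was 0.0405 for Ide and 0.0266 for ENSMUSG00000045999 (6.73, SE 0.91) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Btaf1 (-0.33, SE 0.052), Olfml3 (-0.49, SE 0.090), Tacr3 (1.09, SE 0.189), Npy2r (0.40, SE 0.086) and Bcl6 (0.42, SE 0.093) had the next smallest p and did not pass, with adjusted p from 0.0545 for Btaf1 to 0.369 for Bcl6 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. None of the 24 genes followed throughout passed, with interactions from -2.26 for Cst7 to 0.73 for App. Of the fixed lists, 15 were lower and 3 higher by camera at the preset correlation, led by interferon response (19 measured, all negative, median -0.80, camera adjusted p = 2.01e-19) and antigen presentation (16, all negative, median -0.62, camera adjusted p = 1.4e-11). Each of the 18 calls was lost, with adjusted p = 0.059 for both of these lists and up to 0.575 with an estimated correlation. Adjusted over the list alone 11 interferon and 4 antigen presentation genes fell, and 0 of either over all genes. In the 8 libraries left without the intermediate ones, 0 genes passed by edgeR's quasi-likelihood test, with 248 at an unadjusted p under 0.05, and 12 lists passed. With the choroid plexus level as a covariate it gave 0 genes, with 668 at an unadjusted p under 0.05. Left out singly, libraries gave from 0 genes, a count first reached without mouse 1, to 36 without mouse 7.

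Averaged over both vectors, mAdu changed 85 genes, 38 higher and 47 lower. Ide (log2 0.30, SE 0.027) and Btaf1 (0.28, SE 0.026) led the higher genes, followed by Rspo2 (0.33), Ppp1r3c (0.26), Tacr3 (0.64), Hspa5 (0.17), Htr1a (0.20), Agt (0.30), Syt4 of synaptic vesicles (0.17) and Serpini1, the neuronal protease inhibitor neuroserpin (0.18). Such an average need not hold with each vector. Ide rose by 0.48 with eGFP and its interaction of -0.36 passed. Tacr3 rose by 1.18 with mVEGF-C and its interaction of 1.09 did not pass. Lower were Lcn2 (-2.02, SE 0.295), C3 (-0.78, SE 0.117), Npas4 (-0.71, SE 0.094), Vwf (-0.46, SE 0.068), Shisa7 (-0.32), Mylk3 (-0.73), Etnppl (-0.46), Dsp (-0.45), Jph1 (-0.24) and Slc8a2 (-0.19). Among these leading genes adjusted p ran from 8.46e-05 for Ide, Btaf1 and ENSMUSG00000045999 (-5.22, SE 0.494) to 0.0248 for Dsp by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Members of lists that fell were H2-K1 (-0.41), Ifit3 (-0.55), C1qc (-0.31), Mal (-0.23), Nrgn (-0.16), Camk2b (-0.14), Tekt1 (-0.43) and Mt1 (-0.21), and Sox11 (0.24) rose. Of the 24 genes followed throughout, C3 and H2-K1 passed and 22 did not, with changes from -1.39 for Cst7 to 0.10 for Aqp4.

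Averaged over vectors, 13 lists were lower with mAdu and 1 was higher. Complement had a median of -0.28 (13 measured), of which 2 fell over all genes and 8 adjusted over the list alone (camera adjusted p = 2.2e-09; adjusted p = 0.0563 with an estimated correlation). Disease-associated microglia had a median of -0.18 (27 measured), of which 0 fell over all genes and 13 adjusted over the list alone (camera adjusted p = 2.2e-09; adjusted p = 0.27 with an estimated correlation). All 14 calls were lost, with adjusted p = 0.0563 for complement to 0.437 for homeostatic microglia with an estimated correlation. By fry with Benjamini-Hochberg adjustment, complement and heat shock (adjusted p = 0.0128 for each) and Fc receptors and reactive astrocytes (0.0488 for each) of the 14 passed. Oligodendrocytes and myelin (17, -0.12), excitatory neurons (16, -0.08) and dentate granule cells (13, -0.07) were lower, and heat shock (14, 0.06) was higher with 1 and 4 that rose by the same counts. The remaining lower lists were interferon response, antigen presentation, Fc receptors, homeostatic microglia, reactive astrocytes, choroid plexus, ependymal cells and glucocorticoid response, with medians from -0.29 to -0.06. Without the intermediate libraries, 1 gene and 13 lists passed; with the choroid plexus level as a covariate, 9 genes passed. The 85 genes kept their direction, with a median absolute log2 change of 0.244 at first and 0.246 and 0.256 in these settings, and a median SE of 0.045, 0.066 and 0.056. When 1 library was left out at a time, 9 genes passed without mouse 12 and 172 without mouse 7.

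Averaged over both antibodies, mVEGF-C changed 58 genes, 37 higher and 21 lower. Of 24 immediate early genes measured, 7 rose over all genes and 14 adjusted over the list alone, and 22 had a positive change (median log2 0.29, camera adjusted p = 1.17e-23; adjusted p = 0.0782 with an estimated correlation). Fos rose by 0.89 (SE 0.112), Egr2 by 1.34 (SE 0.20), Fosb by 0.66 (SE 0.122) and Arc, a regulator of synaptic plasticity, by 0.61 (SE 0.095). Arc was at 137 ± 33.4 and 128 ± 3.29 CPM with eGFP and at 205 ± 16.7 and 200 ± 33.9 CPM with mVEGF-C. Ttr fell by 1.39 (SE 0.169), at 51.6 ± 21.9 and 56.2 ± 8.99 CPM with eGFP and 25.3 ± 5.28 and 16.6 ± 2.24 CPM with mVEGF-C. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 0.00319 for Fos, for Ttr and for ENSMUSG00000045999 (-3.91, SE 0.466), 0.0116 for Egr2, 0.0148 for Arc and 0.0307 for Fosb. Mobp (0.29), Bcas1 (0.28), Arl5b (0.26), Ppp1r3c (0.23), Rngtt (0.23), Arrdc3 (0.21), Washc4 (0.18), Homer1 (0.24), Cyp51 (0.15) and Hspa5 (0.14) rose. Hc (-1.33), 1500015O10Rik (-0.69), Col23a1 (-0.54), Tacr3 (-0.54), Carmil3 (-0.28), Plppr3 (-0.28), Fxyd6 (-0.26), Timp2 (-0.18) and Slc6a7 (-0.17) fell. For Tacr3 the change was -1.09 with mIgG and the interaction 1.09, which did not pass, so its average may rest on the mIgG mice. Of the 24 genes followed throughout, Ttr passed and 23 did not, with changes from -0.96 for Cst7 to 0.25 for App. The App value includes mouse 5 of eGFP+mAdu, in which App was low.

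Other lists also moved with mVEGF-C on average, 3 higher and 8 lower with immediate early genes included. All 18 meningeal and perivascular fibroblast markers were negative (median log2 -0.41, camera adjusted p = 1.21e-12), with 0 that fell over all genes and 14 adjusted over the list alone, and the call was lost (adjusted p = 0.296 with an estimated correlation). The other 9 calls were lost too, with adjusted p = 0.0637 for choroid plexus to 0.723 for disease-associated microglia with an estimated correlation. By fry with Benjamini-Hochberg adjustment, immediate early genes, choroid plexus and heat shock passed (adjusted p = 0.0246 for each). Ependymal markers (11, all negative, median -0.35), border-associated macrophage markers (4, all negative, median -0.42) and choroid plexus markers (12, 10 negative, median -0.24) were lower, with 7, 4 and 5 that fell adjusted over the list alone and 0, 0 and 2 over all genes. Antigen presentation (-0.13), complement (-0.11), reactive astrocytes (-0.14) and disease-associated microglia (-0.07) were lower, and oligodendrocytes and myelin (0.05) and heat shock (0.07) higher. Without the intermediate libraries, 0 genes passed by edgeR's quasi-likelihood test, with 842 at an unadjusted p under 0.05, and 12 lists passed. Log2 changes of all genes fell with GC content in this comparison (Spearman's rho -0.43 across genes, which are not independent replicates), and the genes that rose had a median GC content of 42.2% and those that fell of 54.4%. With a correction for GC content and length 29 genes passed, of which 25 were among the 58, and with the choroid plexus level as a covariate 5 passed, of which 2 were. The 58 genes kept their direction, with a median absolute log2 change of 0.246 at first, 0.249 without the intermediate libraries and 0.264 with the covariate, and a median SE of 0.042, 0.063 and 0.074. When 1 library was left out at a time, 4 genes passed without mouse 9 and 253 without mouse 7, and the list count ran down to 8 without mouse 7.

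The level of App was compared between mice because the strain carries an amyloid precursor protein transgene. The App counts do not separate the mouse gene from the transgene. App (chromosome 16, 84949685 to 85173766, mm10, ENSMUSG00000022892) was at 5236 ± 96 CPM in eGFP+mIgG, 3515 ± 2080 CPM in eGFP+mAdu, 4834 ± 143 CPM in mVEGF-C+mIgG and 5364 ± 135 CPM in mVEGF-C+mAdu. Prnp, the prion protein gene, was at 1184 CPM in mouse 5 and 2448 CPM in mouse 6, against 3036 to 3434 CPM in the other 10. Lamr1-ps1, a pseudogene that lies next to Prnp on chromosome 2, had 0 reads in mouse 5 and 5.88 CPM in mouse 6, against 7.42 to 11.9 CPM in the other 10. Mouse 4 of the same group was at 5487, 3336 and 10.3 CPM for these 3 genes.

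**Figure D4:**
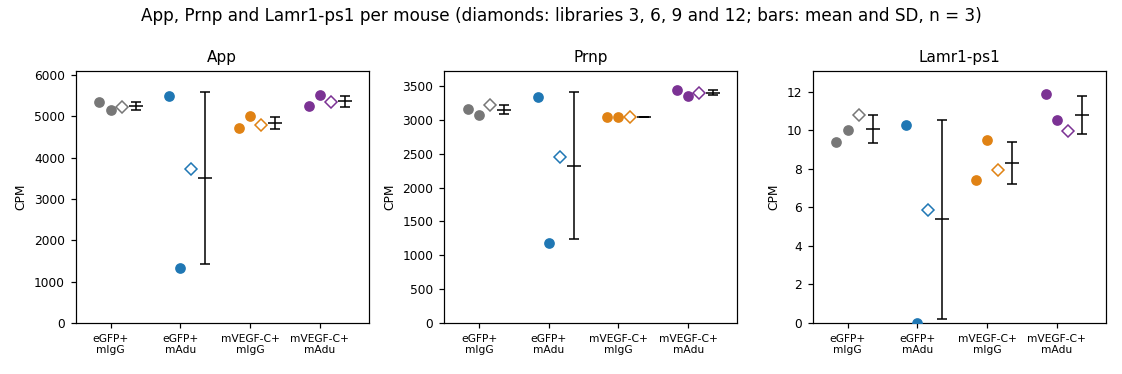
Points give CPM per mouse of App, Prnp and Lamr1-ps1 in the 4 groups (open diamonds for libraries 3, 6, 9 and 12), with bars for the mean and SD of 3 mice. In eGFP+mAdu, mouse 4 stood at 5487 CPM of App, mouse 5 at 1342 CPM and mouse 6 between them at 3716 CPM.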

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

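The test of copy number and the counts over other splits of the samples were chosen after the results were seen. The interaction asks whether the mAdu effect differed between vectors, and 2 genes passed by edgeR's quasi-likelihood test and 18 lists by camera at the preset correlation. None of the 18 lists passed with an estimated correlation (lowest adjusted p = 0.059), and chance was not excluded for either count. Groups of 3 mice are too small for a test of single outlying samples.

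For genes, ENSMUSG00000045999 had an interaction of 6.73 and Ide of -0.36 on the log2 scale. The former rests on mice 1 to 3, in which the identifier took 8.59%, 8.51% and 2.44% of the reads. For fixed lists, the median interactions below 0 were -0.80 for interferon response, -0.62 for antigen presentation, -0.56 for choroid plexus, -0.56 for T and NK cells, -0.45 for striatum, -0.34 for ependymal cells, -0.28 for complement and -0.26 for reactive astrocytes. Smaller ones were -0.20 for homeostatic microglia, -0.19 for disease-associated microglia, -0.15 for Fc receptors and phagocytosis, -0.12 for mitochondrially encoded genes, -0.11 for oligodendrocytes and myelin, -0.10 for inhibitory neurons and -0.07 for ribosomal proteins. Above 0 were 0.47 for border-associated macrophages, 0.11 for dentate granule cells and 0.07 for cholesterol synthesis. By camera with an estimated correlation 0 of all 39 lists passed, with 9 at an unadjusted p under 0.05. By fry 0 of the 39 passed, with 9 at an unadjusted p under 0.05. Of 50 splits of the 12 mice, the real one included, 3 gave at least 2 genes and 3 gave at least 18 lists. The highest of the others were 13 genes and 18 lists, and their medians 0 genes and 11 lists.

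Ide and Btaf1 are neighbours on chromosome 19 and both were higher in eGFP+mAdu, by 0.48 and 0.45. A copy-number gain of one contiguous segment that holds both genes would raise the genes between them as well. The highest change between them was that of March5, at 0.115 (SE 0.047), and Cpeb3 was at -0.058, which argues against such a gain. The 16 genes tested outside the pair had a median of -0.001, from -0.446 for Myof (SE 0.116) to 0.253 for Htr7 (SE 0.080). Among these 16 was Ppp1r3c, at 0.239 (SE 0.053), which did not pass here but passed in the combination. It lies near Btaf1 on chromosome 19, from 36731731 to 36736653. Fgfbp3, beside Btaf1, was at 0.319 (SE 0.104, adjusted p = 0.377 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). A gain of only parts of the segment was not tested. An effect of the antibody and a variant carried by mice of that group may both stay open, and neither was tested.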

How the results depend on the processing

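Settings that left out sets of libraries or corrected for GC content and length were chosen after the data were seen. Values follow 1 order: mAdu with eGFP, mAdu with mVEGF-C, mVEGF-C with mIgG, mVEGF-C with mAdu, the combination, the interaction, mAdu averaged and mVEGF-C averaged. The counts of genes were 5, 31, 6, 7, 324, 2, 85 and 58, and of lists 11, 12, 10, 16, 14, 18, 14 and 11. With DESeq2 size factors every count stayed within 1.5 times (311 genes for the combination). The setting without a filter moved nothing, since the filter removed no gene. No paired analysis was possible because the replicate numbers 1 to 12 are each used once. Except where a reason is given, the cause was not tested.

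The DESeq2 Wald test gave 47, 126, 20, 119, 455, 8, 237 and 155 genes. Limma-voom with quality weights gave 507, 1234, 937, 970, 2660, 220, 1681 and 1789. Fits of only the 2 groups compared gave 7, 6, 2, 62 and 610 for the first 5 comparisons.

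With the choroid plexus level as a covariate, 4, 0, 9, 0, 2, 0, 9 and 5 genes passed by edgeR's quasi-likelihood test, with 1361, 952, 1037, 756, 1043, 668, 1599 and 886 at an unadjusted p under 0.05. This level was lower in each mVEGF-C+mAdu mouse (-0.731 to -0.22) than in any other mouse (-0.079 to 0.333). In contrasts with that group, covariate and treatment are confounded, and lost calls do not show a choroid plexus cause. The genes called at first kept their direction, with a median absolute change of 0.485, 0.703, 0.948, 0.319, 0.262, 3.55, 0.244 and 0.246 before and 0.476, 0.533, 1.013, 0.459, 0.252, 3.69, 0.256 and 0.264 after. Their median SE was 0.052, 0.124, 0.134, 0.048, 0.055, 0.482, 0.045 and 0.042 before and 0.053, 0.208, 0.134, 0.091, 0.103, 0.714, 0.056 and 0.074 after, with a smaller change for mAdu with mVEGF-C and almost no rise of the SE for mAdu with eGFP and mVEGF-C with mIgG. The covariate gave 14, 15, 14, 8, 12, 10, 17 and 8 lists, of which 11, 9, 8, 5, 7, 7, 11 and 3 were among the original ones. The GC content and length correction gave 5, 38, 8, 4, 98, 2, 106 and 29 genes. For the combination 83 of the 324 genes remained, and the 241 lost had a median absolute change of 0.229 before and 0.161 after, with a median SE of 0.051 and 0.048. Their calls thus ended because the changes shrank.

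For lists, an estimated correlation left 0, 5, 0, 1, 3, 0, 0 and 0, with 5, 9, 3, 9, 9, 9, 9 and 5 at an unadjusted p under 0.05. Fry gave 0, 9, 0, 3, 9, 0, 4 and 3, with 7, 12, 4, 13, 11, 9, 13 and 10 at an unadjusted p under 0.05.

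Without libraries 3, 6, 9 and 12 the counts of genes were 2, 0, 2, 0, 2, 0, 1 and 0 by edgeR's quasi-likelihood test, with 377, 683, 263, 758, 1275, 248, 872 and 842 at an unadjusted p under 0.05. List counts were 11, 13, 6, 15, 13, 12, 13 and 12. Without libraries 1, 4, 7 and 10 they were 5, 131, 25, 14, 70, 16, 64 and 49 genes, and without libraries 2, 5, 8 and 11 they were 238, 212, 26, 588, 1281, 11, 711 and 576. These 3 settings leave the same number of libraries, so fewer samples do not account for the difference between them. Without libraries 3, 6, 9 and 12, the genes called at first kept their direction, with a median absolute change of 0.474, 0.718, 0.925, 0.31, 0.271, 3.5, 0.246 and 0.249. Their median SE was 0.082, 0.179, 0.19, 0.074, 0.081, 0.49, 0.066 and 0.063, higher than before except for the interaction, where it was almost the same. Libraries 3, 6, 9 and 12 lay near the midpoint of the other 2, so leaving them out could hardly move a group mean. Kept direction and size are thus no check in this setting. The biological coefficient of variation rose from 5.16% to 7.21% and residual degrees of freedom fell from 8 to 4. Why the 2 calls of the interaction were lost was not tested. Without libraries 5 and 6 the counts were 6, 34, 7, 49, 192, 0, 43 and 122, with 1143 genes at an unadjusted p under 0.05 for the interaction. The group eGFP+mAdu is then mouse 4 alone and the spread comes from the other groups, so these counts are no check of the comparisons that use that group.

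Leaving out 1 library at a time gave genes from 4 (without mouse 1) to 35 (2), 2 (9) to 138 (7), 1 (9) to 52 (7), 0 (4) to 110 (5), 12 (12) to 594 (7), 0 (1) to 36 (7), 9 (12) to 172 (7) and 4 (9) to 253 (7), with the mouse left out in parentheses. Where several omissions gave the same count, only the first mouse is named. Lists ran from 11 to 14, 12 to 17, 6 to 13, 16 to 19, 13 to 15, 14 to 18, 12 to 16 and 8 to 15. No named gene that passed in either fit changed direction in any setting. Among those that passed in neither, 8 values changed sign without libraries 3, 6, 9 and 12. Over the single libraries left out, 3271 values of named genes kept their side of the threshold, 688 lost it and 40 gained it, while 105 that passed in neither fit changed sign. The smallest changes simulated for the combination were recovered in 41% of genes with 12 libraries and in 26% with 8, which limits what small changes can show. These shares assume independent libraries with the dispersions of all 12, so the share for 8 may be too high.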

Other observations

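All tests in this part were chosen after the results were seen, except that counts for fixed lists were planned.

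Libraries 3, 6, 9 and 12 lay between the other 2 libraries of their group in 84.6% or more of 1055, 1072, 1917 and 693 varying genes. Reads merged after sequencing are argued against in libraries 3, 6 and 9, where 9, 6 and 11 genes lay outside the range of the other 2 libraries by more than 6 counting SDs and 10%, and stay open in library 12, where 0 did. Material mixed before sequencing may account for the pattern, with weights of 0.48 to 0.58 for one of the other 2 mice. In library 6, the weights of library 4 were 0.57, 0.59 and 0.57 in App, Prnp and Lamr1-ps1. ENSMUSG00000045999 lay outside the range in library 3, at 24410 CPM against 91440 and 91830 CPM in libraries 1 and 2. So did Gm42418 (132 against 298.2 and 283.5 CPM) and Lars2 (9.46 against 19.06 and 18.08 CPM). All 3 were high together in libraries 1 and 2. Whether their levels arose before or after any mixing was not tested, so they do not decide on mixing. Separate mice that differ along one axis always have one in the middle, and the chance that it has the same place in the numbering in all 4 groups is 0.037. In 100000 normal draws of such mice, the middle one lay as near the midpoint as here in all 4 groups with a chance of 0.58. These draws assume 1 axis shared by all genes, which was not tested. In simulated separate libraries whose genes varied independently, libraries 3, 6, 9 and 12 held the middle value in 31.9% to 33.6% of varying genes. In simulated mixtures they held it in 99.8% to 100%. The real shares lay between, so separate mice stay open where they differ along such an axis. Mixing and separate mice of that kind cannot be told apart by these values. If material was mixed, each group would hold fewer independent mice than 3 and each p would be too small.

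App in library 5 was at 25.6% of the median of the 10 libraries other than 5 and 6, and Prnp at 37.2%, and Lamr1-ps1 had 0 reads. A technical loss is argued against, since only these 3 of 11057 genes lay that low in library 5. The treatment is argued against by library 4 of the same group, with App at 5487 CPM. Fewer copies of the transgene, or none, in mouse 5 may account for the pattern, and this was not tested directly. The 37 genes within 1 Mb of App and Prnp had a median difference of 0.016. That argues against a loss of the regions around these genes, but cannot show a change of the transgene. No genotype is given in the sources used here beyond the strain.

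Other splits of the same mice were counted. For 3 against 3 mice there are 10 splits, too few for a share under 0.05. In the order mAdu with eGFP, mAdu with mVEGF-C, mVEGF-C with mIgG, mVEGF-C with mAdu and the combination, the real counts of genes were 5, 31, 6, 7 and 324 and the highest others 0, 1, 363, 0 and 0. For lists the real counts were 11, 12, 10, 16 and 14 and the highest others 17, 17, 15, 16 and 18. The medians of the other splits were 6, 9, 7, 11 and 8 lists. Splits as large, the real one included, were 1, 1, 2, 1 and 1 for genes and 4, 4, 2, 2 and 2 for lists. The split with 363 genes set mice 1, 3 and 7 against mice 2, 8 and 9, and a count that high points to a structure of the samples other than the groups. The neocortex list level followed this split, at -0.209, -0.076 and -0.35 in mice 1, 3 and 7. In mice 2, 8 and 9 it was at 0.088, 0.359 and 0.061. Levels of other lists, interferon response among them, followed the split too, and the cause was not tested. For the averaged effects, 1 of 50 splits, the real one, gave as many genes as the 85 for mAdu (highest other 1) and the 58 for mVEGF-C (highest other 46). These splits shuffled the labels of all 4 groups at once. They cannot tell the named treatment from any other difference between the groups, and so do not exclude chance for it. They also treat the 12 libraries as separate mice, which the intermediate libraries leave open. For their 14 and 11 lists chance was not excluded either, with 16 and 22 of 50 splits as large and 20 and 18 as the highest others. The medians of the others were 11 and 10 lists.

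By camera at the preset correlation, lists that passed in no comparison were astrocytes, oligodendrocyte precursors, endothelial cells, pericytes and smooth muscle, lymphatic endothelial cells, CA1 and CA3 pyramidal cells, synapse, neurogenesis and cell cycle, thalamus, neocortex, APP processing and amyloid clearance, circadian clock and proinflammatory cytokines. The lowest adjusted p among them was 0.0618 by camera with Benjamini-Hochberg adjustment, for pericytes and smooth muscle with mVEGF-C averaged.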
